A study of Homo sapiens with 12 samples.

How the data were processed

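The series holds 12 libraries of human leukaemia cell lines: 7 KDM2B ChIP-seq libraries, 1 per line, and 5 input libraries. Per the labels, cells were grown in IMDM with 10% FBS and immunoprecipitated with a KDM2B antibody from Millipore. Only the KDM2B peak lists were analysed; input signal was not used here. Among the samples used here no input was listed for DND41 and JURKAT, and which control each list was called against is not given in the sources used here. Per the submitters' processing notes, reads were checked with FastQC 0.10.1 and aligned with Bowtie 1.1.1, and the build is hg19. The peak names in the files point to MACS, whose version, control and threshold are not given in the sources used here.

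Each list gives a chromosome, start, end, name and score per peak. The score is the authors' own value per peak, as deposited, with no unit stated; it was read as a transformed MACS p-value by the convention of early MACS lists. Scores were used only to rank or filter peaks, as percentiles within a list, except for the alternatives with a common floor or a pooled median score, which assume one scale. The lowest score differed between lists (50 in K562, REH, SUP-B15 and JURKAT, 60 in DND41, and 80 in HPB-ALL and SIL-ALL, as whole numbers), so the lists did not share one cut-off. Peak names ran without gaps, no peak overlapped another of its list, and no peak end exceeded the hg19 chromosome length. The sequencing depth of the libraries is unknown; deeper or better enriched libraries give longer lists, and no interval could be given for a peak's presence. Intervals of shares of peaks are Wilson 95% intervals and cover counting error only.

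Each line was 1 group with 1 list. Lineage is not in the labels and was taken from background knowledge of the named lines. The 4 T-ALL lines were compared with the 3 other lines by exact permutation over the 35 splits of 7 lines into 4 and 3, two-sided on the difference of means for peak number and width and one-sided for phi (within higher); the smallest p is 0.0286. Because each line is a single culture, these p-values measure the spread between lines and libraries together. Benjamini-Hochberg adjusted values were computed over the 7 lineage comparisons: peak number, width, covered length, lowest score, G-light share, share of regions of a line alone, and phi.

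Peaks of all lists that overlapped by at least 1 bp were merged into regions, and a region was counted for a line with any peak in it. Sharing was set against 100 shuffles of each list within its chromosomes, outside centromeric, variable and stalk bands, which describe random placement and ignore mappability and gene density. The similarity of 2 lines was the phi coefficient of called or not called over the merged regions. In data simulated with list lengths as in the real lists and 200 regions planted in the T-ALL lines only, 200 were recovered, as were 700 of 700 planted in all lines and 196 of 200 planted in the other lines only. Planted copies overlap by construction, so this checks the counting only. With those unequal lengths the simulated phi difference was -0.0185 (exact permutation p = 0.943, one-sided), so phi missed the planted regions. With lists of one length it was 0.0398 (exact permutation p = 0.0286). These lists also held fewer random peaks, so the effects of unequal length and of random peaks cannot be told apart.

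Regions named in the text were chosen by a rule written before the data were examined: the 5 with the highest mean within-list percentile of the best peak among regions of all lines, of T-ALL lines only, of the 3 other lines only and of both B-ALL lines only, and the 3 highest of each line alone. All 21 regions chosen for 1 line alone are in the results, and the text gives the first of each line and, for REH and SUP-B15, the other named region of the same band. Bands, arms and chromosome X were examined after the data were seen. Positions are hg19 coordinates, counted from 1, and band names come from the hg19 cytoband table of the R package circlize 0.4.16 by the midpoint of the peak or region.

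The annotation used here was a gene table of GRCh38.p14, another build than that of the lists, and no hg19 gene annotation or sequence was used here. Peaks were therefore not assigned to genes, and the planned tests of promoter share, CpG content and 16 gene lists were not run. Genes in the text are background on a band. The table gave only the share of protein-coding genes per chromosome.

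Alternatives were equal lists of the 5942 top-scored peaks, peaks at or above the median score of each list or of all lists, a 500 bp merging distance, autosomes alone, 50% reciprocal overlap, the Jaccard index of bases, T-ALL against B-ALL lines, and each line left out. A common score floor, the highest of the 7, was added after the data were examined, because the lists had different floors. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.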

Results

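KDM2B is a JmjC-domain histone demethylase whose CXXC zinc finger binds unmethylated CpG-rich DNA and which belongs to a variant Polycomb repressive complex. Its genomic binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in 7 human leukaemia cell lines. K562 comes from a chronic myeloid leukaemia in blast crisis and carries the BCR-ABL1 fusion. REH and SUP-B15 are B-cell precursor acute lymphoblastic leukaemia (B-ALL) lines. DND41, HPB-ALL, JURKAT and SIL-ALL are T-cell acute lymphoblastic leukaemia (T-ALL) lines. Each line had 1 KDM2B library and 1 peak list, so no line had a replicate and the cell lines served as the units of every comparison between lineages. The number of reads behind each list is unknown. Lineages are background knowledge of the lines, and the 4 T-ALL lines were set against the 3 other lines.

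The T-ALL lines had about 2.01 times as many KDM2B peaks as the other lines, and 1.63 times as many when peaks within 500 bp of each other were counted as 1 (8669 against 5304, a difference of 3365 in place of 7256). The lists held 14944 peaks in DND41, 12765 in HPB-ALL, 14839 in JURKAT and 15304 in SIL-ALL, against 5942 in K562, 8146 in REH and 7533 in SUP-B15. The mean was 14463 ± 1149 peaks (SD, n = 4) in the T-ALL lines and 7207 ± 1138 (SD, n = 3) in the others, and the lists did not overlap in length. The two-sided exact permutation test over the 35 splits of the lines gave p = 0.0286, the smallest value this design allows. The lowest score was 80 or above in HPB-ALL and SIL-ALL, 60 in DND41 and about 50 in the other lists, so DND41, HPB-ALL and SIL-ALL were listed above a higher floor than K562, REH and SUP-B15. A common floor, the highest of the 7, left 9572 peaks in DND41, 12757 in HPB-ALL, 7406 in JURKAT and 15304 in SIL-ALL, against 3239 in K562, 2794 in REH and 3372 in SUP-B15. The mean difference was then 8125 peaks, and the exact permutation p was 0.0571, above the threshold of 0.05. Over the 7 comparisons of T-ALL with other lines that were computed, each p of 0.0286 had a Benjamini-Hochberg adjusted value of 0.0667 in this exact permutation scheme, so none passed the adjustment.

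**Figure D1:**
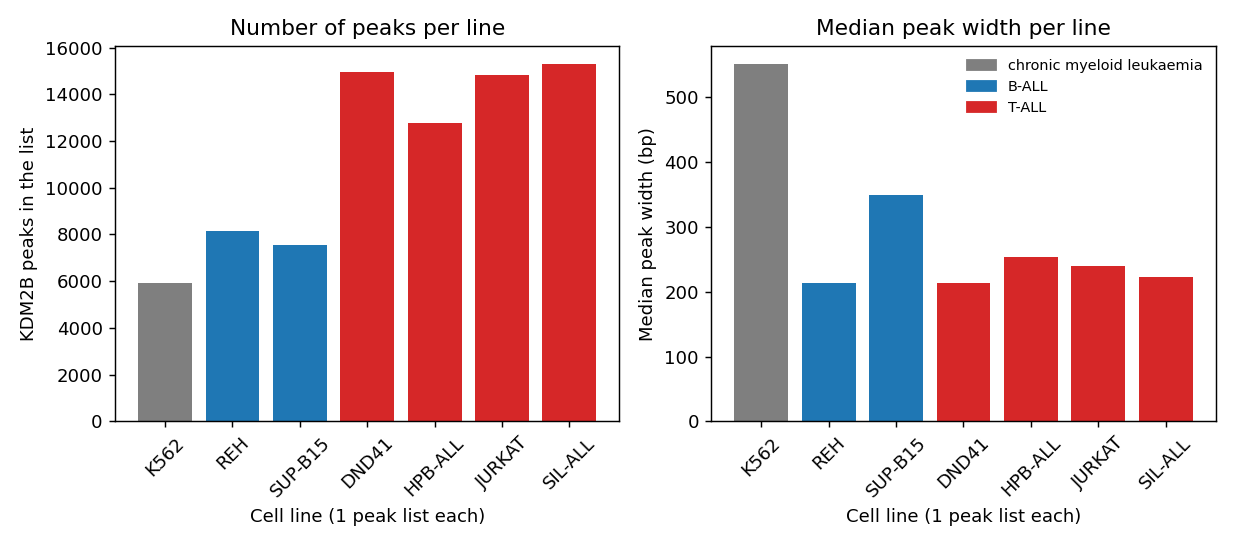
Number of KDM2B peaks (left) and median peak width in bp (right) for each of the 7 cell lines, 1 peak list per line, coloured by lineage. The 4 T-ALL lines hold 12765 to 15304 peaks, the other lines 5942 to 8146, and K562 has the widest peaks.

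Peaks were widest in K562, with a median of 552 bp, followed by SUP-B15 with 350 bp. REH had the same median width as DND41, 213 bp, and the other T-ALL lines had 253 bp (HPB-ALL), 240 bp (JURKAT) and 223 bp (SIL-ALL). The mean of the medians was 232 ± 17.8 bp (SD, n = 4) in T-ALL lines and 372 ± 171 bp (SD, n = 3) in the others, a difference that did not pass the threshold (exact permutation p = 0.143, two-sided). The difference, T-ALL minus other, was -139 bp with all lines and -49.3 bp without K562. With equal lists of 5942 top-scored peaks it was -6.75 bp (exact permutation p = 0.886), and with a common floor -269 bp (exact permutation p = 0.0571). The peaks covered 4.51 ± 0.259 Mb in T-ALL lines (n = 4) and 3.27 ± 1.11 Mb in the others (n = 3), and this difference did not pass the exact permutation test (p = 0.0571).

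A core of peak regions was common to all 7 lines. The 7 lists merged into 29071 regions, of which 709 (2.44%) held a peak of every line and 12147 (41.8%) a peak of 2 or more lines. When the peaks of each list were placed at random on their own chromosomes, 851 ± 27.8 regions (SD over 100 shuffles) were shared by 2 or more lines and none by all 7. Random placement ignores mappability and gene density, and input signal was not used. Sharing beyond it therefore does not by itself show common KDM2B binding. The all-line regions were most frequent in bands 12q24.31 (14 regions), 11q13.1 (12) and 17q25.3 (11). The region with the highest mean score percentile lay in 16p11.2 (hg19, chromosome 16, 30668770 to 30672892) and stood at or above percentile 99.9 in every list. It was followed by a region in 16p13.3 (chromosome 16, 3199300 to 3201165; mean percentile 99.5) and one in 17q25.3 (chromosome 17, 75953200 to 75956715; mean percentile 99.4). The next lay in 1q25.3 (chromosome 1, 181057490 to 181059681) and 10q22.2 (chromosome 10, 76583895 to 76586486). In all-line regions the median of the mean score percentile was 87.9 over the T-ALL lines and 70.4 over the other lines. Percentiles are ranks within a list, and the T-ALL lists are longer, so these values do not compare the strength of the sites. The size of the core depended on the lists: it was 402 with 5942 top-scored peaks per list, 288 with peaks at or above each list's median score and 276 with a common floor. It was 21 when 50% reciprocal overlap with the shortest list, that of K562, was required. K562 also had the widest peaks, with a median of 552 bp against 213 to 350 bp in the other lists. A peak narrower than 50% of a K562 peak cannot meet this requirement, so the 21 depends on peak width too. Without REH, 1072 regions were common to the remaining 6 lines.

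**Figure D2:**
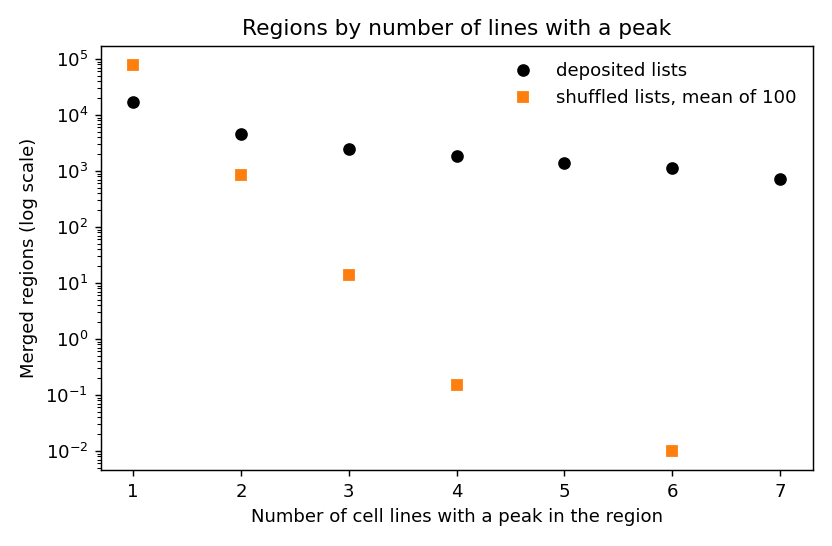
Merged regions (log scale) by the number of cell lines with a peak in them, in the deposited lists (circles) and as the mean of 100 random placements (squares; means of 0 are not drawn). Regions with a peak of all 7 lines number 709, and none arose in the shuffled lists.

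Binding sites exclusive to the T-ALL lines were far more frequent than sites exclusive to any other set of 4 lines. In 655 regions all 4 T-ALL lines had a peak and K562, REH and SUP-B15 had none, while the other sets of 4 lines had at most 102 such regions (DND41, HPB-ALL and SIL-ALL with SUP-B15). They were part of 3073 regions with a peak in all 4 T-ALL lines, of which 836 also had a peak in 1 of the other lines, 873 in 2 and 709 in all 3. The strongest T-ALL region lay in 12q24.31 (chromosome 12, 122710898 to 122712552; mean percentile 96.9), with scores of 935 in DND41, 814 in HPB-ALL, 348 in JURKAT and 739 in SIL-ALL. The next lay in 7p22.3 (chromosome 7, 1979766 to 1980723; mean percentile 95.7), 12q22 (chromosome 12, 95610487 to 95611541; 95.5), 2p11.2 (chromosome 2, 85765773 to 85767000; 95.5) and 14q32.31 (chromosome 14, 101908361 to 101909553; 94.9). Bands with the most T-ALL regions were 11p11.2 (7 regions) and, with 6 each, 6p22.3, 17q25.3, 16q22.1, 19p13.2 and 11p15.4. The median mean percentile of the T-ALL regions was 60.4, against 87.9 for the all-line regions in the same lines. Of the 35 splits, the lineage split alone gave a count as large (share 0.0286). The count was 177 with equal lists (at most 72 in other splits) and 414 with peaks at or above each list's median score (at most 81), and with 6 lines it was 1033 without SUP-B15, 1007 without DND41 and 1059 without JURKAT. With a common floor, which also shortened the lists of K562, REH and SUP-B15, it was 727 (at most 142 in other splits).

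**Figure D3:**
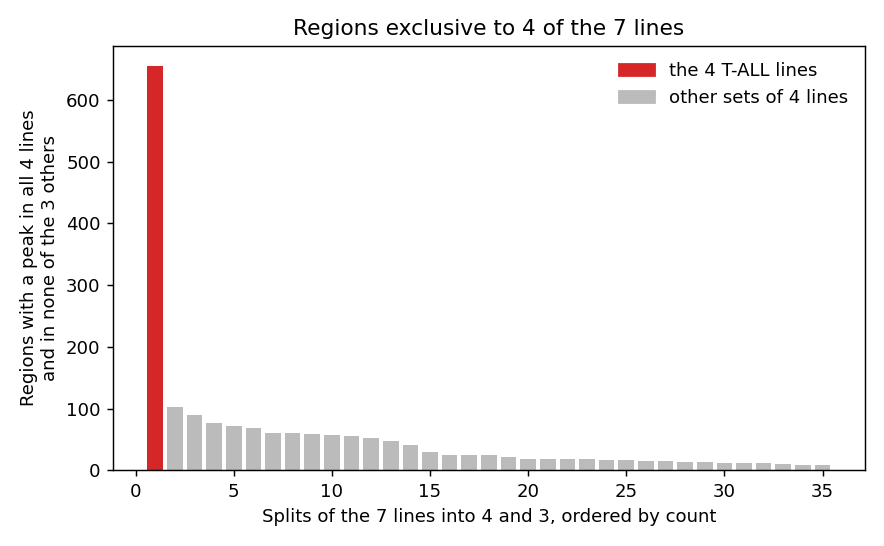
Number of merged regions with a peak in all lines of a set of 4 and in none of the remaining 3 lines, for each of the 35 sets, ordered by count. The T-ALL set (red) has 655 regions and the next set 102.

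The reverse pattern comprised 56 regions, which had a peak in K562, REH and SUP-B15 and in no T-ALL line, 4.55% of the 1230 regions with a peak in all 3, and 709 of the 1230 were bound in all 4 T-ALL lines too. As many or more regions were found in 8 of the 35 splits, with a median of 40 and up to 387 in other sets, so the count did not stand apart. The highest of these counts (387, 343, 308 and 242) came from sets of 3 T-ALL lines, whose lists are longer. With equal lists the count was 84, beside 177 T-ALL regions. As many or more were then found in 4 of the 35 splits (highest other 127), so it did not stand apart there either. The strongest region of this kind lay in 12q13.12 (chromosome 12, 49738423 to 49741692; mean percentile 99.5), with scores of 768 in K562, 637 in REH and 1074 in SUP-B15. The others were in 2p21 (chromosome 2, 46524002 to 46527348; mean percentile 97.0), a band that holds the hypoxia factor gene EPAS1, 2q14.3 (chromosome 2, 127863285 to 127865131; 96.7), 22q13.2 (chromosome 22, 42309861 to 42311528; 96.4) and 3q27.1 (chromosome 3, 182970981 to 182972287; 95.4). The median mean percentile of the 56 regions was 71.4. Their count was 32 with a common floor, 389 without K562, 139 without REH, 168 without SUP-B15 and 113 without JURKAT.

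REH and SUP-B15 shared 312 regions that none of the other lines had, whereas pairs of T-ALL lines shared 365 to 606, K562 shared 106 with REH and 80 with SUP-B15, and pairs of a T-ALL line with another line shared 59 to 215. With equal lists REH and SUP-B15 shared 319 regions alone and the T-ALL pairs 95 to 198, so the order of these turned, while K562 shared 153 with REH and 130 with SUP-B15 and the pairs of a T-ALL line with another line shared 58 to 182. These counts leave out regions that a further line has. A T-ALL pair thus loses regions shared with other T-ALL lines, whereas the set has no further B-ALL line, so the counts do not rank the similarity of pairs. In the same equal lists phi was 0.233 to 0.338 for T-ALL pairs and 0.115 for REH with SUP-B15. The strongest B-ALL region lay in 17p11.2 (chromosome 17, 17626682 to 17628285; mean percentile 99.3). The second lay in 6p25.3 (chromosome 6, 391584 to 394306; mean percentile 98.8), the band of the lymphoid transcription factor gene IRF4, with scores of 272 in REH and 698 in SUP-B15. The remaining 3 were in 7q32.1 (chromosome 7, 127671228 to 127672884; mean percentile 97.9), 21q22.3 (chromosome 21, 44818331 to 44820241; 97.6) and 19q13.33 (chromosome 19, 50935090 to 50936857; 97.5). Peaks were not assigned to genes, so whether any of these regions overlaps a gene of its band was not determined.

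On average, lines of the same side shared more of their sites than lines of different sides. The phi coefficient of calling over the merged regions averaged 0.196 over pairs within the T-ALL lines or within the other lines and 0.0948 over pairs between them (difference 0.102; exact permutation p = 0.0286, one-sided). With the lists as deposited, phi among T-ALL pairs was highest for DND41 with HPB-ALL (0.256) and lowest for JURKAT with SIL-ALL (0.154). REH with SUP-B15 reached 0.206, and SIL-ALL with REH, the lowest of the 21 pairs, stood at -0.00576. With lists of equal length the T-ALL pairs had a mean of 0.283, from 0.233 (HPB-ALL with JURKAT) to 0.338 (DND41 with SIL-ALL). In those lists REH with SUP-B15 had 0.115, no more than SUP-B15 with DND41 (0.188), SIL-ALL (0.120) or JURKAT (0.115), and the pairs of K562 with the B-ALL lines averaged 0.0278, below the 0.0791 of the pairs between the sides. With a common floor the difference was 0.0724 and the exact permutation p was 0.0571.

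**Figure D4:**
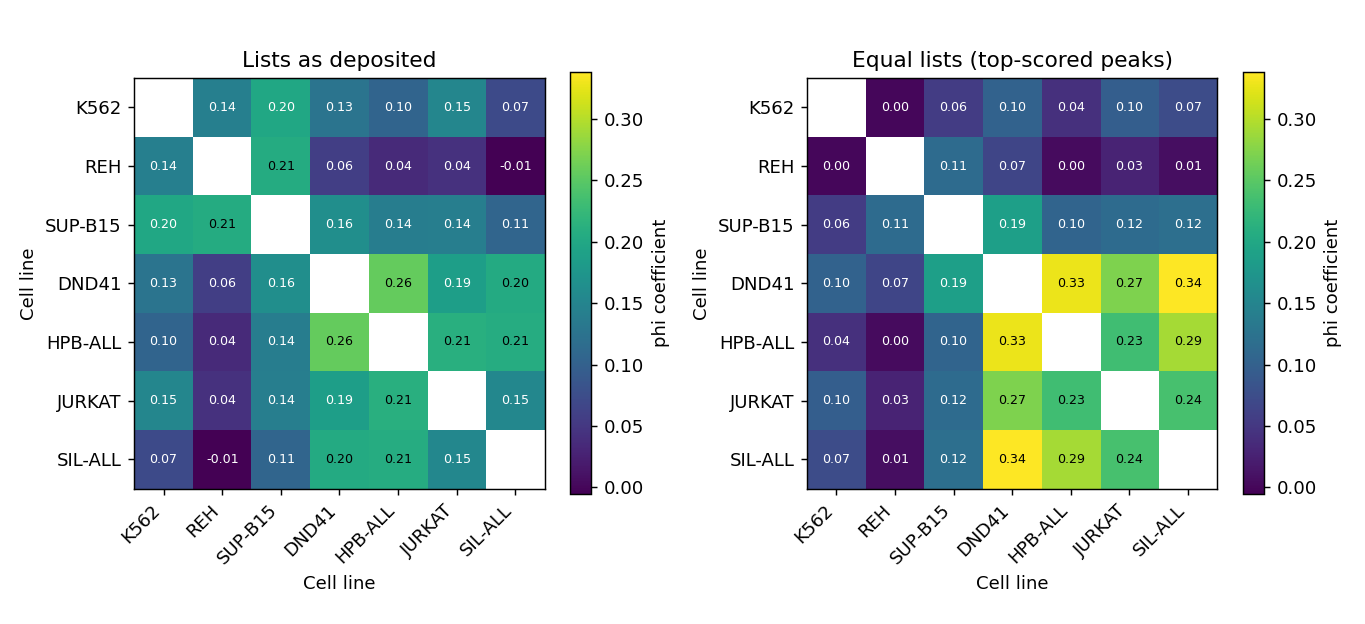
Phi coefficient of calling over merged regions for each pair of the 7 lines, with the lists as deposited (left) and with the 5942 top-scored peaks per list (right). The T-ALL pairs average 0.203 on the left and 0.283 on the right.

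Each line also had sites of its own: 16924 regions (58.2%) held a peak of 1 line alone. By mean score percentile the strongest were in 13q33.3 in K562 (chromosome 13, 108516611 to 108521709; score 1211), 17q21.33 in REH (chromosome 17, 48263650 to 48264277; score 926) and 8q24.3 in SUP-B15 (chromosome 8, 144508554 to 144511897; score 1214). Among T-ALL lines they were in 2q14.3 in DND41 (chromosome 2, 128785281 to 128786052; score 486), 1p36.22 in HPB-ALL (chromosome 1, 9788387 to 9789289; score 1032), 21q21.3 in JURKAT (chromosome 21, 28216323 to 28217661; score 816) and 20q13.33 in SIL-ALL (chromosome 20, 61590370 to 61591861; score 1315). The first and second REH regions were neighbours, the second at 48263107 to 48263468 on chromosome 17. In SUP-B15 another of the named regions lay in 8q24.3 too, at 140714812 to 140717194 on chromosome 8. The strongest DND41 region stood at percentile 96.0 of its list, below the 98.4 to 99.9 of the other lines. Without replicate libraries, a site of 1 line cannot be separated from a site of 1 library.

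The lists followed the gene-rich part of the genome. Giemsa-light bands, which make up 42.2% of the hg19 sequence and tend to be gene-rich, held 65.5 ± 1.07% of the peaks in T-ALL lines (n = 4) and 69.0 ± 0.918% in the others (n = 3; exact permutation p = 0.0286, two-sided), a comparison added after the data were examined, and its p was 0.0571 with equal lists. The band with most peaks was 19p13.3 in REH (180) and DND41 (272), 16p13.3 in K562 (120) and SIL-ALL (263), and 17q25.3 in SUP-B15 (177), HPB-ALL (174) and JURKAT (167). The lines departed from one another on single chromosome arms. HPB-ALL had 60 peaks on 3p, 0.470% of its list (Wilson 95% interval 0.365 to 0.605%) against a median of 2.28% over the lines, and 0.168% in place of 0.470% with equal lists. It had 1.31% on 16p (1.13 to 1.52%) against 2.78%. It was high on 4q, with 3.09% (2.80 to 3.40%; median 1.93%), and on 9p, with 1.16% (0.988 to 1.36%; median 0.687%). REH had 1.01% on 3p (0.812 to 1.25%) and 2.60% on 21q (2.28 to 2.97%; median 1.33%), and SUP-B15 had 4.43% on 8q (3.99 to 4.92%; median 2.55%). K562 was low on 20p (0.320%, interval 0.205 to 0.499%), 17p (0.724%, 0.538 to 0.973%), 9p (0.269%, 0.166 to 0.437%), 13q (0.926%, 0.712 to 1.20%) and 12p (0.572%, 0.410 to 0.798%), and high on 1p (9.31%, 8.59 to 10.1%) and 7q (4.59%, 4.09 to 5.16%). These intervals cover counting error only, and copy number and the control libraries were not used here.

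**Figure D5:**
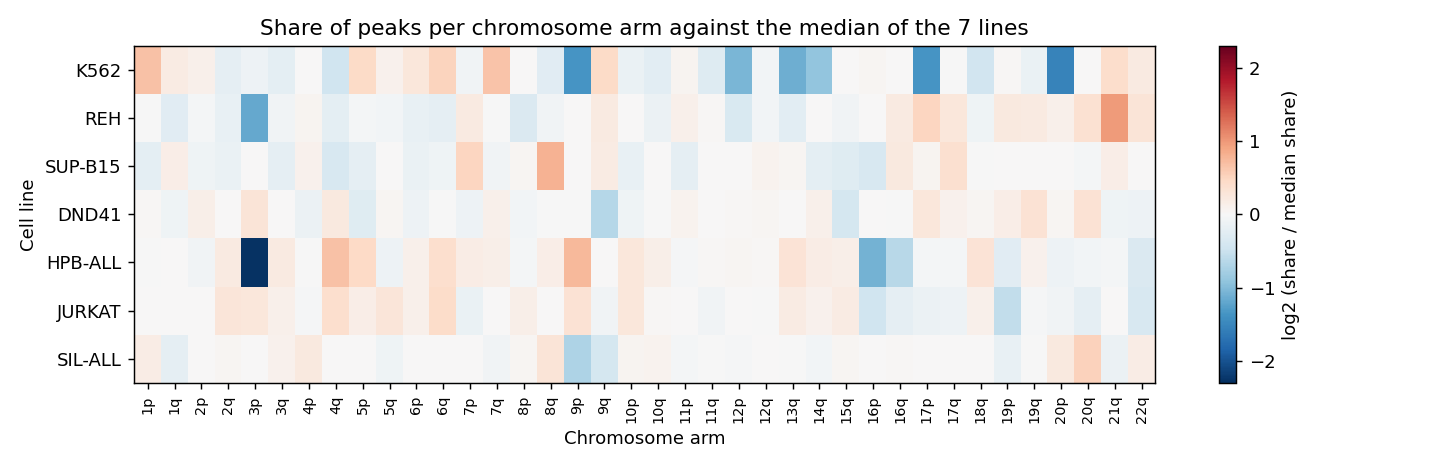
Share of each line's peaks on each autosomal arm, as log2 of its ratio to the median share of the 7 lines (arms with a median share of at least 0.5%). HPB-ALL on 3p has the lowest ratio, and K562 is low on 9p, 12p, 13q, 17p and 20p.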

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

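Over the 7 lines, 44 values per line were examined for a line standing far from the others, and 6 were found against 2.2 by chance; the choice of arms was made after the data were seen. Of these, 5 belong to K562, the only line in the set that is not lymphoid. Its median peak width was 552 bp, next to 350 bp in SUP-B15 and down to 213 bp. It had 9.31% of its peaks on 1p (next 6.60%, lowest 5.03%) and 4.59% on 7q (next 3.19%, lowest 2.76%). Its share was lowest on 11q, 3.06% (next 3.59%, highest 3.85%), and on 20p, 0.320% (next 0.862%, highest 1.08%). The sixth is REH, with 2.60% of its peaks on 21q (next 1.75% in K562, lowest 1.21%); REH had 144 peaks in 21q22.3, 1.77% of its list. Copy number, which a chromosome gain or loss in a line would change, was not used here, and no explanation was tested for these values.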

How the results depend on the processing

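The common score floor, and the results on G-light share, bands and arms with their alternatives, were chosen after the data were examined. Of 103 alternative values other than those of the named regions, 54 kept their direction and side of the threshold or moved little, 26 kept their direction and lost the threshold, 23 moved, and none reversed. Counts and arm shares could only stay or move, so a reversal was possible only for the differences between lineages. For peak number, leaving out K562 and comparing T-ALL with B-ALL lines are the same computation, counted under each name. The named regions have high scores, so equal lists and a common floor could not change their lines. The 500 bp merging distance was applied here within each list, so it could add a line to a named region but not remove one, and it added none. Alternatives for promoter share, CpG content and gene lists were not run, since peaks were not assigned to genes. No paired analysis was possible because each line has 1 list.

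With each line left out, the smallest p those designs allow is 0.0667 or 0.1, so the loss of the threshold there follows from fewer lines: the difference ranged from 6624 to 7822 for peak number, from 0.0674 to 0.117 for phi, and from -4.10 to -3.16 percentage points for G-light share. Merging within 500 bp gave a peak number difference of 3365. Width differences with a line left out ran from -219 to -49.3 bp, all-line regions from 724 to 1072, T-ALL regions from 880 to 1059 and regions of the other lines from 64 to 389. T-ALL against B-ALL lines gave 6624 peaks, in a design whose smallest p is 0.0667.

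With a pooled median score as floor the peak number difference was 6089 and with a common floor 8125 (exact permutation p = 0.0571 for both). The common floor, which shortened every list but that of SIL-ALL, gave 276 all-line regions, 32 regions of the other lines and a phi difference of 0.0724 (exact permutation p = 0.0571). Equal lists gave a width difference of -6.75 bp, 402 all-line regions, 7066 regions of 2 or more lines, 177 T-ALL regions, 84 regions of the other lines, a G-light difference of -3.22 percentage points (exact permutation p = 0.0571) and 51 bands higher in every T-ALL line. Peaks at or above each list's median gave 288 all-line regions, 7079 regions of 2 or more lines and 414 T-ALL regions. Reciprocal overlap with the list of K562, which has the widest peaks, gave 21 all-line regions. Equal lists moved HPB-ALL to 0.168% on 3p and 0.252% on X; the common floor moved REH 21q to 3.22%, SUP-B15 8q to 6.02% and K562 1p to 10.3%. Shorter lists hold fewer peaks by construction, but exclusive regions can rise in number, since the lists that must lack a peak lose peaks too. The T-ALL regions numbered 727 with a common floor (at most 142 in other splits) in place of 655. The regions of the other lines numbered 84 with equal lists in place of 56. Other causes were not tested. Unknown depth limits every count of sites seen in some lines and not in others.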

Other observations

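Predictions for some of the tests below were written after the results were seen. These were the tests of equal lists, score floors, chance for regions, random loss on 3p and gene share of X. The bands were picked after their values were seen. Over 640 cytogenetic bands with at least 20 peaks, 84 had a higher share of the peaks in every T-ALL line than in any other line, where chance separates 2.86% of bands; 51 did with equal lists and 59 with peaks within 500 bp merged. The ratio of mean shares was highest in 4q28.2 (10.2), 13q13.3 (7.15) and 2q21.3 (6.07), bands with few peaks. The bands that follow were picked because they hold known genes of T cells or histones, so they show no theme among the 84, and enrichment of such genes was not tested. As members of the 84 they separate the lines fully, so their p with the lists as deposited lies at or near its smallest value and only restates that choice. In 10p14, the band of GATA3, a transcription factor of T-cell development, the T-ALL lists had 22 (DND41), 28 (HPB-ALL), 46 (JURKAT) and 29 (SIL-ALL) peaks, against 5 in K562, 6 in REH and 4 in SUP-B15, or 0.217 ± 0.0690% of peaks (n = 4) against 0.0703 ± 0.0158% (n = 3; exact permutation p = 0.0571). Band 2q33.1 held 0.274 ± 0.0354% against 0.0994 ± 0.0327%, and 2q33.2, the band of the T-cell co-receptor genes CD28 and CTLA4, 0.0864 ± 0.00435% against 0.0230 ± 0.0148% (exact permutation p = 0.0286 for both). Band 11q23.3, which holds the CD3 genes, had 0.437 ± 0.0463% against 0.295 ± 0.0215% (exact permutation p = 0.0286), and 6p22.2, with histone genes, 0.174 ± 0.0605% against 0.0473 ± 0.0296% (exact permutation p = 0.0571). With equal lists 10p14 and 2q33.1 (exact permutation p = 0.0571 for both) stayed higher in every T-ALL line, so 2q33.1 lost the threshold, and 2q33.2, 11q23.3 and 6p22.2 did not stay so. With a common floor only 11q23.3 among these bands lost this. The ratio of mean shares then rose from 3.08 to 7.56 in 10p14, from 2.75 to 5.15 in 2q33.1 and from 3.68 to 8.52 in 6p22.2. It fell from 3.76 to 3.49 in 2q33.2 and from 1.48 to 1.32 in 11q23.3.

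In the other direction 38 bands were higher in K562, REH and SUP-B15. The share of 9q was lower in the T-ALL lines, with 2.21% (DND41), 3.48% (HPB-ALL), 3.30% (JURKAT) and 2.61% (SIL-ALL) of the peaks against 3.94% (SUP-B15) to 4.70% (K562) in the others. This was not particular to 9q: the share of 21q was lower too, and those of 2q, 3q, 4q and 18q were higher, in every T-ALL line. Differences of arm shares between the lineages were not tested. The bands 9q33.2, 9q33.3, 9q34.11 and 9q34.2 are among the 38, while 9q21.13 and 9q21.2 are among the 84. Band 9q34.3, which holds NOTCH1, a gene often mutated in T-ALL, had 0.466 ± 0.0347% of the peaks in T-ALL lines (n = 4) and 0.871 ± 0.0216% in the others (n = 3; exact permutation p = 0.0286). Band 21q22.3 had 0.616 ± 0.0470% and 1.29 ± 0.411% (exact permutation p = 0.0286). Both bands stayed lower in every T-ALL line, at the same p, with equal lists, a common floor and a 500 bp merging distance. Band 12q13.13, with 0.290 ± 0.0265% and 0.466 ± 0.0790% (exact permutation p = 0.0286), did not stay so with equal lists (exact permutation p = 0.114) or a common floor (exact permutation p = 0.0857). These p-values were not adjusted over the 640 bands. The bands were taken from those that separate the lines fully, so their p with the lists as deposited lies at or near its smallest value and only restates that choice. In 9p21.3, the band of CDKN2A, K562 had 0 peaks, REH 1, SUP-B15 3, DND41 3, HPB-ALL 17, JURKAT 8 and SIL-ALL 4. Band 16p13.3 held 24 peaks in HPB-ALL and 83 to 263 in the other lines.

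As many separated bands as the 84 came from 1 of the 35 splits, the lineage split itself (at most 39 in other splits). The highest other split had 23 against 51 with equal lists and 39 against 59 with 500 bp merging. A share of 1 in 35 is the smallest this design allows, so the 84 bands stand apart only at that unadjusted level. The 38 bands in the other direction were matched by 5 of the 35 splits (up to 42 bands), so chance cannot be excluded for them.

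The T-ALL lines had 655 regions of their own. Of the 35 splits 1, the lineage split itself, had as many, and the highest other had 102. That is the smallest share the design allows, without adjustment. The T-ALL lists are also the 4 longest, so this share alone cannot tell chance from list length. Longer T-ALL lists as the whole cause are argued against by the 177 regions left with equal lists (at most 72 in other splits). Lower score floors are argued against, as far as scores share 1 scale, since 0 of the 4 T-ALL lists had a floor under the highest of the other lists. With top-quarter peaks required in all 4 lines, 39 regions were counted (at most 8 in other splits), so not all were weak in the T-ALL lists. This rank holds no signal of K562, REH or SUP-B15 below their floors, so it cannot decide whether sites were missed there. Weak sites missed in those 3 lists stay open. Lost arms are argued against as the whole cause by the 91.0% of regions (596) outside the 9 arms low in K562, REH or SUP-B15. A lineage difference in KDM2B binding is a hypothesis that may explain them; a difference in depth, enrichment, control or culture batch between the T-ALL libraries and the others stays open, as do the 56 regions of the other lines, which 8 of 35 splits matched (highest other 387).

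HPB-ALL had few peaks on 3p. Of 102 regions on 3p with a peak in the 3 other T-ALL lines, HPB-ALL had a peak in 25.5%, against 81.7% of 3731 elsewhere (Fisher's exact test, two-sided, p = 3.28e-31 after Bonferroni adjustment over the 266 arm shares from which this one was picked as the lowest ratio), so random loss of independent sites is argued against. A missing or under-represented segment may be the cause: the longest run of regions without an HPB-ALL peak was 19, from 5028254 to 16926448 on chromosome 3 (3p26.1 to 3p24.3), and a run as long came up in random orders with p = 0.0522 (10000 permutations). A segment and a loss spread over the arm cannot be told apart with 102 regions. Fisher's test here rests on 1 HPB-ALL library, so its p does not measure the spread between libraries or cultures. No biological explanation was tested.

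Chromosome X held few peaks in every line, 0.221% (REH) to 0.797% (SIL-ALL). The highest upper bound, 0.951%, lies below its 4.23% of protein-coding genes (GRCh38.p14), so a low number of genes is argued against. Lower scores of X peaks may contribute. With the 7 lists pooled, X held 0.808% of the peaks below each list's median score and 0.307% of those at or above it (Fisher's exact test, two-sided, p = 5.45e-22). This test counts peaks of different lines as independent, although lines share sites, so its p does not measure the spread between lines. The direction was the same in 7 of 7 lines. Copy number and mappability of X stay open, and no biological explanation was tested.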
